A study of Homo sapiens with 6 samples.

How the data were processed

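The series compared 2 stable HEK293 Tet-On lines, 1 carrying a control vector and 1 carrying a myocilin vector, on 3 Affymetrix HG-U133 Plus 2.0 arrays each. HEK293 is an established human embryonic kidney line, and in a Tet-On line doxycycline switches the inserted gene on. The labels' protocols, worded alike for both lines, describe 0.2 or 1 µg/ml doxycycline for 48 h and extraction of total RNA with Trizol. The labels do not give the dose behind each array, and only the myocilin samples carry a description that names doxycycline, so a difference in exposure to the drug between the lines is not excluded. Each array was placed in its group by its source name. Titles end in running numbers, 1 to 3 for control and 7 to 9 for myocilin, which no arrays share between groups, so replicates were numbered in accession order and were not paired. These numbers run with the groups, so any order of handling they reflect cannot be told apart from the lines; arrays with other numbers are not analysed here. Nothing in the labels says that the arrays of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each line is represented once, and an effect of myocilin cannot be separated from other differences between the lines.

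The deposited table holds 41751 probe sets with positive and negative values on a log scale, which were read as log2; the base is inferred from the values and is not stated by the authors. The background correction, probe summarisation and normalisation are not given in the sources used here. Every array has a median of 0, and 57.3% of probe sets hold an exact 0 on at least 1 array, while the median over the 6 arrays is within 1e-06 of 0 for 4.9% of them. From these values, each probe set appears to have been centred by the authors on a reference level that is not the median of these 6 arrays, though no source states it. The centring removes brightness, so levels of different probe sets cannot be compared, no detection call could be made, and a low value cannot be told from background. The table holds 0 platform control probe sets. The direction of the values was settled by MYOC, which was higher on the arrays labelled myocilin. Precision is limited by the number of arrays, 3 per group.

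Of the probe sets, 39188 were listed in the platform annotation, 37460 with 1 gene and 1728 with several; the other 2563 were not listed and are unnamed here. Entrez identifiers of 37416 probe sets with 1 gene matched the RefSeq gene table of GRCh38.p14, which gave current symbols and chromosomes, and 44 kept the annotation's symbol. This gave 18338 genes, of which 9841 had more than 1 probe set and 18265 lay on chromosomes 1 to 22 or X. A gene's value was the mean of its probe sets, since the planned choice of the brightest probe set cannot be made on centred values. The planned filter on dim probe sets, the pseudocounts, the brightness criterion for naming genes and the RNA quality check on control probe sets were not run for the same reasons. Centring each array on its median moved nothing, because the medians were already 0.

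Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; a 2-fold change was an absolute log2 difference of at least 1. All differences are myocilin minus control. Gene lists, 39 in number, were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry (statmod 1.5.0). Chromosomes were tested as sets in the same way. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took MYOC, the 12 largest rises and the 12 largest falls past the threshold without overlap between groups, up to 4 members of each list by p, and 5 reference genes. Genes named outside this rule are marked as chosen after their values were seen.

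The gene fit was tested on simulated data for this comparison over 18338 genes. It recovered 34.3% of 67 genes changed by 0.3 log2 units, 77.6% of 67 at 0.5 and 97% of 66 at 1, with 7 false calls among 146. Far fewer genes were changed than were called in the real comparison. The adjusted threshold was therefore stricter, and these rates do not carry over to that comparison. For lists shifted by 0.2, camera recovered 2 of 2 and called 0 other lists and 0 chromosomes. Noise was drawn independently for each gene, so the simulation could not show false calls that arise from genes moving together. Alternatives tried were quantile normalisation, median centring, eBayes with trend and robust fitting, array weights, probe sets ending in _x_at or _s_at left out, a Welch test per gene, other set tests and each array left out in turn. After seeing the data, 3 more were added: 1 probe set per gene picked by its ID, each gene minus the median of its 50 nearest chromosomal neighbours, and lists without chromosomes 6, 10, 16 and 18.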

Results

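Transcript levels were measured in HEK293 cells carrying an inducible myocilin vector or the control vector, with 3 arrays per line. The study's title concerns cell proliferation, survival and the ERK pathway, the growth factor signalling cascade of RAF, MEK and ERK kinases, and the comparison asks which transcripts differ between the 2 lines. Values are the authors' centred values on the log2 scale, so they show differences between arrays and not absolute levels. The arrays had standard deviations of 0.17 to 0.20 over probe sets. Across probe sets, correlations were 0.409 to 0.464 between control arrays, 0.513 to 0.608 between myocilin arrays and -0.244 to -0.00516 between the groups. The first principal component held 61.6% of the variance and separated the lines, with control arrays at -16.8 to -12.5 and myocilin arrays at 12.98 to 15.6. No pair of arrays was a duplicate, the standard deviation of the difference within a line being 0.154 to 0.191.

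MYOC, the induced gene, encodes a secreted olfactomedin-domain protein of the eye's trabecular meshwork. Its only probe set read -6.71, -8.32 and -8.29 on the control arrays and 0.21, 0.20 and 0.24 on the myocilin arrays. The means were -7.77 ± 0.92 and 0.22 ± 0.02 (SD, n = 3 each). The log2 difference was 7.99 with a standard error of 0.35, 254.5-fold at face value (limma adjusted p = 4.7007e-06). The table does not show whether the control level lay above background, so this fold rests on values that may sit at the array's floor.

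Of 18338 genes, 2866 (15.6%) changed, 1519 higher and 1347 lower in the myocilin line. Most differences were small, with a median absolute log2 difference of 0.32 among the changed genes, and 59 genes changed at least 2-fold, 28 up and 31 down. At the level of probe sets, 4603 of 41751 changed, 2280 up and 2323 down, and 132 changed at least 2-fold. Among probe sets outside the gene table, 208 of the 2563 unlisted and 184 of the 1728 with several genes changed. Groups did not overlap for 34.9% of genes, against 10% by chance. The planned test that uses each gene's own variances, separately for each line, called 44 genes. The count was 1878 without probe sets ending in _x_at or _s_at, which tests fewer genes, and 1613 without myocilin array 1, 1889 without control array 2 and 1905 without myocilin array 2.

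**Figure D1:**
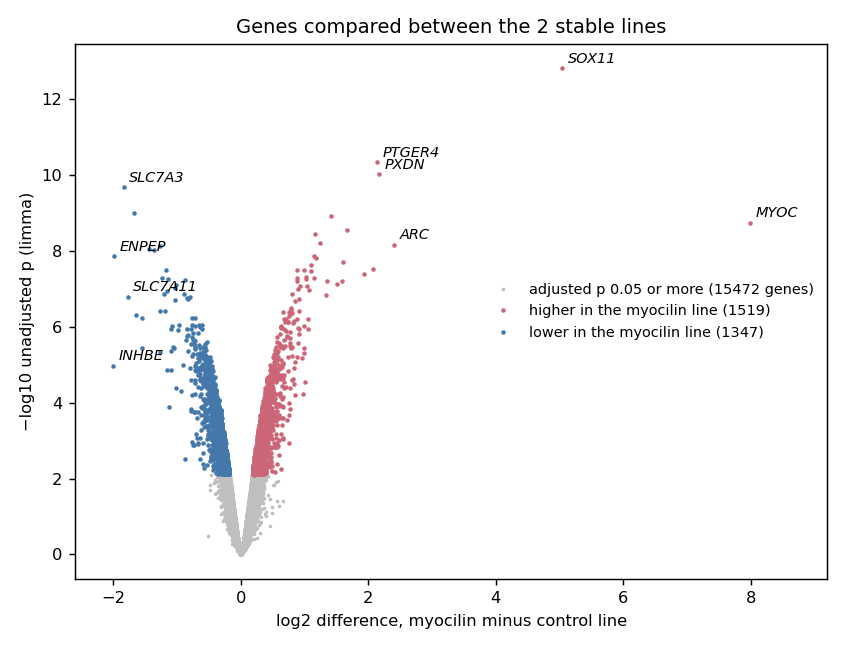
Each point is a gene, with the log2 difference between the myocilin and control lines on the x axis and -log10 of the unadjusted limma p on the y axis. Coloured points are the 1519 genes that rose and the 1347 that fell; MYOC and SOX11 lie farthest to the right, at 7.99 and 5.04.

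After MYOC, the largest rise was that of SOX11, a transcription factor of neural progenitors, by 5.04 ± 0.08 (log2, SE) or 32.9-fold (adjusted p = 2.842e-09). All of its 3 probe sets rose, by 4.35 to 5.47. ARC, a neuronal immediate early gene, rose by 2.40 ± 0.12, and PXDN, a peroxidase that cross-links basement membrane collagen, by 2.17 ± 0.07. PTGER4, a prostaglandin E2 receptor, rose by 2.14 ± 0.06, and PLA2G4A, the phospholipase that releases arachidonic acid for prostaglandin synthesis, by 1.94 ± 0.12. TCEAL7 rose by 2.07, the histone gene H4C8 by 1.67, the progesterone receptor gene PGR by 1.60, MID1IP1 by 1.59, PWWP3B by 1.51, the neurofilament gene NEFM by 1.42 and TRIM47 by 1.34. For 3 of these genes the probe sets differed in size: PTGER4 gave 3.27 and 1.01, PGR 2.64 and 0.55, and NEFM 2.66 and 0.17, the last not past the threshold (adjusted p = 0.177).

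The largest fall was that of INHBE, an activin subunit gene, at -2.00 ± 0.23 (log2, SE, adjusted p = 0.000876). ENPEP, an aminopeptidase that cleaves angiotensin II, fell by 1.99 ± 0.11. SLC7A3, a transporter of cationic amino acids, fell by 1.84 ± 0.06, and SLC7A11, the cystine and glutamate exchanger, by 1.77 ± 0.13. The potassium channel gene KCNK2 fell by 1.68, LINC02806 by 1.65, CHAC1, which encodes an enzyme that degrades glutathione, by 1.55 and the interferon-induced gene IFI44L by 1.55. TAF7L fell by 1.45, MFAP2 by 1.36, CHRDL1, an antagonist of bone morphogenetic proteins, by 1.27 and RTN1 by 1.27. Of the reference genes, GAPDH differed by -0.10 (adjusted p = 0.248), ACTB by -0.03, HPRT1 by -0.06 and PPIA by -0.07, none past the threshold, while TBP rose by 0.21 (adjusted p = 0.0443).

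**Figure D2:**
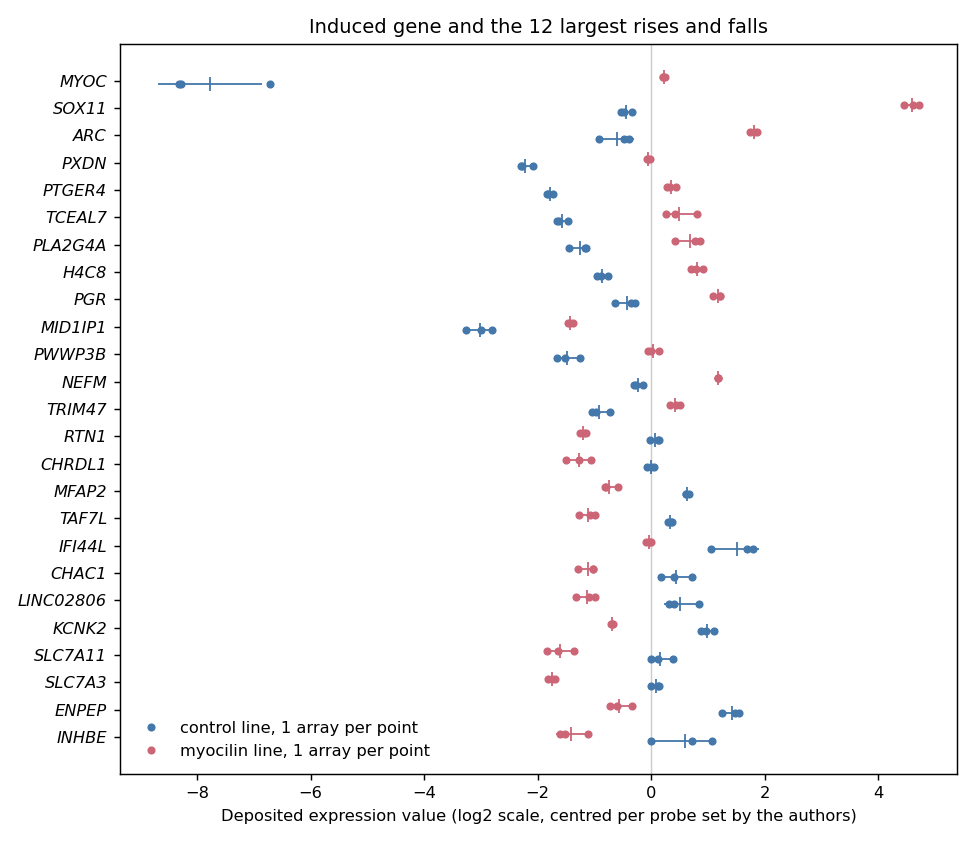
Deposited log2 values of MYOC and the 12 largest rises and falls, 1 point per array; bars are the mean and SD of 3 arrays. The rule for naming these rises and falls required that the lines do not overlap, and the control arrays spread most for MYOC, from -8.32 to -6.71.

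Genes listed as driven by the transcription factor ATF4, which answers amino acid shortage and other stress, and genes of amino acid synthesis mostly fell. Of 32 measured, 25 fell and 0 rose (29 and 1 adjusted over the list alone), with a median log2 difference of -0.44. SLC7A11 and CHAC1 are described above, DDIT4, an inhibitor of mTORC1 signalling, fell by 1.08 ± 0.09 and STC2, a secreted glycoprotein, by 1.09 ± 0.11 (log2, SE). The ATF4 list mean was 0.16, 0.40 and 0.06 on the control arrays and -0.38, -0.39 and -0.31 on the myocilin arrays. ATF4-branch genes kept in the ER list went both ways: PPP1R15A rose by 0.75 and DDIT3 fell by 0.73. Chosen after their values were seen, HERPUD1 fell by 0.37, while ATF4 at -0.21, ATF3 at 0.05 and EIF2AK3 at 0.05 did not pass the threshold. ERN1, also chosen in this way, encodes the sensor of a separate branch but was grouped with these genes. It read 0.0007 and did not pass the threshold. Camera called the list down at the preset correlation (adjusted p = 4.976e-19). Its genes moved together between arrays, with an estimated correlation of 0.725, and the call was lost with an estimated correlation (adjusted p = 0.461). None of the 8 lists called at the preset correlation was called with an estimated one. These losses cannot be put down to correlation alone. The histone list, estimated at -0.0321 and so below the preset 0.01, still went from an unadjusted camera p of 1.477e-06 to 0.0061. Camera takes its degrees of freedom from the arrays with an estimated correlation, and from the genes at a preset one. With 3 arrays per line, the losses therefore also reflect the small number of arrays.

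The list of genes induced by ERK signalling and ERK feedback genes was shifted up in the myocilin line. Of 33 measured, 15 rose and 1 fell (18 and 2 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 1.111e-05, adjusted p = 0.318 with an estimated correlation). EPHA2, an ephrin receptor, rose by 1.06 ± 0.10 (log2, SE), the growth regulator MYC by 0.67 ± 0.08, and the AP-1 and related factors FOSL1 by 0.80 ± 0.10 and MAFF by 0.53 ± 0.07. The gene that fell, EPHA4 at -0.33, was named after its value was seen. Also chosen after their values were seen, the feedback genes DUSP4, DUSP5 and SPRY4 rose by 0.45, 0.59 and 0.51 and the induced factors ETV4, ETV5 and EGR1 by 0.61, 0.42 and 0.56, while DUSP6 and SPRY2 differed by 0.10 and 0.07 and FOS by 0.07, none of these 3 past the threshold. The kinases, adaptors and receptors of the cascade itself showed no joint shift: 2 of 32 rose and 1 fell (the same counts adjusted over the list alone, adjusted p = 0.966). EGFR rose by 0.37, ERBB3 by 0.44, and the exchange factor gene SOS1 fell by 0.21. Their probe sets differed in size, from 0.06 to 0.97 for EGFR, 0.04 to 0.94 for ERBB3 and -0.41 to -0.06 for SOS1. Among the 92 named genes with several probe sets, 8 had probe sets over 1 log2 unit apart and 0 had probe sets past the threshold in opposite directions. Of 33 growth factors and ligands, 3 rose and 6 fell (4 and 6 adjusted over the list alone, adjusted p = 0.686), among them INHBE, described above, PDGFD at -0.53, PDGFC at -0.43 and LIF at 0.40.

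Genes of proliferation and survival moved in both directions, and camera called none of these lists. Of 34 genes of G1/S and DNA replication, 5 rose and 7 fell (6 and 7 adjusted over the list alone, adjusted p = 0.635), including TYMS at -0.39, MCM2 at -0.38, MCM6 at -0.48 and MCM10 at 0.32. Of 30 genes of G2/M and mitosis, 4 rose and 1 fell (7 and 6, adjusted p = 0.635): CENPE was the gene that fell, at -0.39, and PLK1 rose by 0.30, TTK by 0.21 and MKI67 by 0.19. CDK inhibitors and quiescence genes rose in 3 and fell in 3 of 18 cases (6 and 3, adjusted p = 0.966), with CDKN1C at 0.36 and KLF4 at 0.28 against CCNG2 at -0.30 and RB1 at -0.26. Among 22 targets of p53, 3 rose and 3 fell (4 and 3, adjusted p = 0.721), with AEN at 0.48, FAS at 0.31, TP53I3 at -0.45 and SESN2 at -1.09. In the pro-survival BCL2 and IAP list 2 of 20 rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.948): BAG3 at 0.78, PIM3 at 0.24, BAG1 at -0.31 and AKT2 at -0.24. The pro-apoptotic list had 4 rises and 4 falls among 32 (4 and 5, adjusted p = 0.714), with TNFRSF10A at 0.50 and FAS up against PMAIP1 at -0.56 and CYCS at -0.34. For the PI3K-AKT cascade and FOXO targets 3 of 26 rose and 5 fell (3 and 5, adjusted p = 0.721), with IRS2 at 0.88, FBXO32 at 0.28, TXNIP at -0.70 and PIK3R3 at -0.61. AKT2 depended on its probe sets and read 0.05 from 1 probe set picked by its ID.

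The list of histone genes was called up by camera at the preset correlation. Of 22 measured among 31 listed, 11 rose, 1 fell and 10 did not pass (14 and 3 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 1.92e-05, adjusted p = 0.238 with an estimated correlation). H4C8 is described above, and H2AC6 rose by 1.33 ± 0.10, H2BC12 by 1.16 ± 0.06 and H2BC6 by 0.91 ± 0.07 (log2, SE). The gene that fell, named after its value was seen, was H2AZ1, a replication-independent variant, at -0.22. The call ended without genes on chromosomes 6, 10, 16 and 18, an alternative chosen after seeing the data (median -0.15, adjusted p = 0.709), where 5 histone genes were left. With chromosomal neighbours subtracted, also chosen after seeing the data, the list was called with a smaller median of 0.21 (adjusted p = 0.000304). Those neighbours include other histone genes, so the smaller median does not measure how much the region contributed. Of the measured members, 17 lie on chromosome 6. The median of these 5 had a 95% bootstrap interval of -0.224 to 0.958, and 1 of them, H2BC21 on chromosome 1, chosen after its value was seen, rose by 0.96 (adjusted p = 0.000669).

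The other called lists moved less. Of 26 genes of cholesterol and fatty acid synthesis 0 rose and 6 fell (0 and 6 adjusted over the list alone, median -0.11, adjusted p = 0.000955, and adjusted p = 0.461 with an estimated correlation), with INSIG2 at -0.53, FDPS at -0.28, SCD at -0.27 and SC5D at -0.27. This call was lost without probe sets ending in _x_at or _s_at (median -0.08, adjusted p = 0.0838). Glycolysis and hypoxia genes had 3 rises and 9 falls among 34 (4 and 10, median -0.10, adjusted p = 0.00377, and adjusted p = 0.461 with an estimated correlation), with the glucose transporter gene SLC2A3 at -1.01, DDIT4 as above, PDK1 at -0.48 and NDRG1 at 0.85. Cytosolic heat shock genes had 7 rises and 2 falls among 20 (9 and 3, median 0.15, adjusted p = 0.0268, and adjusted p = 0.461 with an estimated correlation), led by the co-chaperone BAG3 and by HSPA1L at 0.58 and HSPB8 at 0.40, with DNAJB6 at -0.44. The probe sets of HSPA1L read 1.09 and 0.06, the latter not past the threshold. HSPB8 read -0.03 without probe sets ending in _x_at or _s_at, and the heat shock call was lost there (median 0.13, adjusted p = 0.484), without control array 1 (0.15, adjusted p = 0.0652), with 1 probe set per gene by ID (0.12, adjusted p = 0.322) and without chromosomes 6, 10, 16 and 18 (0.11, adjusted p = 0.163). For ER chaperones and the unfolded protein response 2 of 34 rose and 5 fell (3 and 9, median -0.10, adjusted p = 0.0309, and adjusted p = 0.461 with an estimated correlation), with XBP1 at -0.39, the chaperone gene CALR at -0.34, DDIT3 at -0.73 and PPP1R15A at 0.75. The ER call was lost without control array 2 (median -0.06, adjusted p = 0.0827), without myocilin array 3 (-0.06, adjusted p = 0.129), under quantile normalisation (-0.07, adjusted p = 0.0592), without probe sets ending in _x_at or _s_at (-0.09, adjusted p = 0.124) and without chromosomes 6, 10, 16 and 18 (-0.10, adjusted p = 0.158), and fry did not call it (adjusted p = 0.0502). Epithelial markers had 3 rises and 0 falls among 15 (4 and 0, median 0.11, adjusted p = 0.00638, and adjusted p = 0.318 with an estimated correlation): the splicing regulator ESRP1 at 1.11, the claudin gene CLDN7 at 1.02 and KRT19 at 0.21. The epithelial median was 0.17 without myocilin array 2 and 0.07 with chromosomal neighbours subtracted, and the list was called in both cases.

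**Figure D3:**
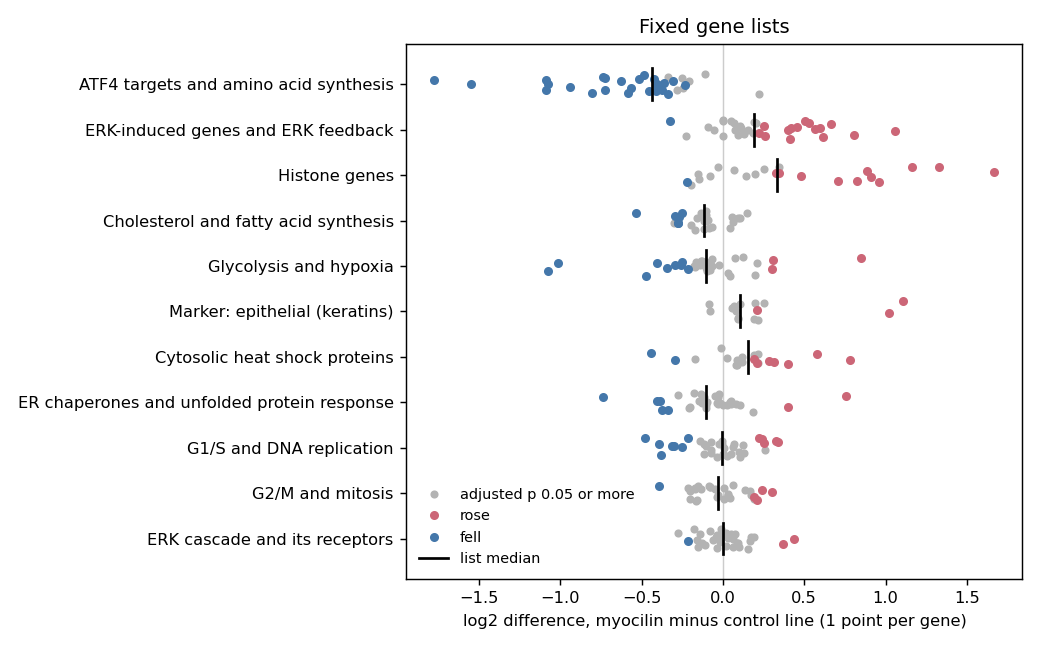
Log2 differences of the measured genes of the 8 lists called by camera and of 3 lists on the cell cycle and the ERK cascade that were not, 1 point per gene, with the list median as a black bar. The ATF4 list lies farthest below 0, at a median of -0.44, and the histone list farthest above, at 0.33.

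Camera called none of the following signalling and matrix lists. Wnt/beta-catenin targets had 6 rises and 4 falls among 28 (6 and 5 adjusted over the list alone, adjusted p = 0.978), with NKD2 at 0.92, MYC as above, LGR5 at -0.76 and APCDD1 at -0.58. Wnt ligands, receptors and modulators had 2 rises and 3 falls among 41 (2 and 3, adjusted p = 0.781), with SFRP1 at 0.79, AXIN1 at 0.48, WNT5A at -0.65 and WIF1 at -0.62. The probe sets of SFRP1 differed in size, from 0.08, not past the threshold, to 1.66. Among 25 members of the olfactomedin family and reported myocilin partners 4 rose and 3 fell (6 and 4, adjusted p = 0.866), including SFRP1, ERBB3, LINGO1 at 0.36 and OLFML3 at -0.47. TGF-beta targets had 3 rises and 5 falls among 25 (3 and 6, adjusted p = 0.1), with TGIF1 at -0.50, LTBP1 at -0.52, ID3 at -0.46 and TIMP3 at 0.33. This list was called down without control array 3 (adjusted p = 0.0391). Extracellular matrix genes had 6 rises and 8 falls among 48 (6 and 8, adjusted p = 0.276), with FBN1 at 0.83, FN1 at -0.45, LAMA1 at -0.48 and LAMB2 at -0.63. Matrix proteases and inhibitors had 3 and 3 among 31 (3 and 3, adjusted p = 0.854), with ADAMTS1 at -1.04 and PLAT at -0.36, and integrins and focal adhesion genes 2 and 3 among 35 (2 and 3, adjusted p = 0.398), with VCL at 0.39 and ITGA4 at -0.50. Actin, SRF and YAP genes had 5 rises and 3 falls among 36 (8 and 3, adjusted p = 0.779), with MYH9 at 0.47 and CNN2 at 0.55. Cell adhesion and junction genes had 5 rises and 8 falls among 33 (6 and 9, adjusted p = 0.635), with CLDN7 as above, CDH11 at 0.86, DSC3 at -0.65 and CDH2 at -0.50. DSC3 and CDH2 lie on chromosome 18, which was lower as a whole. The rise of CDH11 rests mainly on 1 of 4 probe sets, at 2.11 against 0.29 to 0.66.

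Camera called none of the following metabolic, immune and other lists. Nuclear-encoded oxidative phosphorylation genes had 0 rises and 3 falls among 41 (0 and 3 adjusted over the list alone, adjusted p = 0.54), NDUFV2 at -0.55, ATP5MC3 at -0.30 and NDUFS1 at -0.29. Mitochondrial ribosome and stress genes had 4 and 4 among 37 (5 and 4, adjusted p = 0.781), with MRPS30 at 0.68 and TSFM at -0.36. Antioxidant and NRF2 targets had 3 rises and 6 falls among 31 (4 and 9, adjusted p = 0.212), with SLC7A11 as above, GPX8 at -0.72 and AKR1C1 at 0.29. Interferon response genes had 9 rises and 2 falls among 39 (10 and 2, adjusted p = 0.158), with TAP1 at 0.61, IRF7 at 0.87 and IFI16 at 0.46 against IFI44L. NF-kB targets had 4 rises and 0 falls among 27 (7 and 1, adjusted p = 0.436): NFKBIE at 0.44, TNFAIP2 at 0.34, SOD2 at 0.48 and RELB at 0.24. Ribosomal protein genes had 1 rise, RPL37 at 0.42, and 1 fall, RPS23 at -0.24, among 35 (the same adjusted over the list alone, adjusted p = 0.712); RPS23 read 0.01 from 1 probe set picked by its ID. Neuronal genes had 5 rises and 5 falls among 30 (8 and 5, adjusted p = 0.526), with NEFM as above, NEFH at 0.67, SYT1 at -0.61 and MAP2 at -0.43, and circadian and glucocorticoid-responsive genes 2 and 2 among 22 (5 and 4, adjusted p = 0.966), NPAS2 at 0.27, DUSP1 at 0.22, NR3C1 at -0.23 and BHLHE40 at -0.33.

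Among the lists of cell type markers, camera called only the epithelial one. Kidney tubule markers had 2 rises and 0 falls among 14, WT1 at 0.28 and AQP1 at 0.26 (0 and 0 adjusted over the list alone, adjusted p = 0.24). Fibroblast markers had 2 among 15, PRRX1 at 0.62 and COL1A1 at 0.25 (2 and 0, adjusted p = 0.866), endothelial markers 1 among 15, EGFL7 at 0.42 (1 and 0, adjusted p = 0.779), and leukocyte markers 1 among 14, CORO1A at 0.47 (1 and 0, adjusted p = 0.54). Of 12 erythroid and hepatocyte markers 0 passed the threshold (0 and 0, adjusted p = 0.635), the smallest p values belonging to HBB at 0.15 and TTR at 0.38. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 13 of the 39 lists. These included 6 that camera did not call, with fry adjusted p = 0.0067 for antioxidant genes, 0.0254 for interferon response genes and for actin, SRF and YAP genes, 0.0195 for NF-kB targets, and 0.0156 for neuronal genes and kidney tubule markers. Their median log2 differences were small, from -0.0046 for antioxidant genes to 0.096 for interferon response genes. With chromosomal neighbours subtracted, the medians of these 2 lists read -0.085 and 0.042.

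The differences were not spread evenly over the chromosomes. Chromosome 18 was lower in the myocilin line: 132 of its 274 genes fell and 4 rose, with a median log2 difference of -0.21. Chromosome 16 was higher, with 214 rises and 7 falls among 777 genes and a median of 0.14, as were chromosome 10 (152 and 20 of 715, median 0.11) and chromosome 6 (228 and 17 of 1006, median 0.09). Camera called 14 of the 23 chromosomes, 7 up and 7 down. Apart from 18, those called down had small medians, from -0.041 on 15 to -0.011 on 13. Camera compares each chromosome with all other genes, and the median over all genes was 0.018. A chromosome can therefore be called down because others were higher. Pairs of arrays within a line reached medians of 0.034 on 13 and -0.024 on 4. With an estimated correlation camera called 13, of which 5 were up and 10 were shared. The calls on 4, 13, 17 and 22 were lost, and 1, 7 and X, called down, were gained, with medians of -0.0029, -0.011 and -0.0070. The adjusted p with an estimated correlation was 0.00768 for chromosome 18, 0.0163 for 16, 0.00768 for 10 and 0.00274 for 6. These 4 chromosomes hold 15.1% of the tested genes and 774 (27%) of the changed ones, and chromosomes 6, 10 and 16 hold 39.1% of all rises. Without genes on these 4 chromosomes, chosen after seeing the data, 5 lists were called. With the median of the 50 nearest chromosomal neighbours subtracted, also chosen after seeing the data, 19 of the 154 genes under the naming rule were no longer past the threshold: TBP, SOS1, PLK1, TTK, MKI67, PIM3, CYCS, LAMA1, NDUFS1, AKR1C1, SOD2, RPS23, BHLHE40, COL1A1, KRT19, EGFL7, and ADAM10, MYL6 and ANKRD1, which are not described above. Of these, PLK1 read 0.20, TTK 0.10, MKI67 0.08, PIM3 0.15, LAMA1 -0.20 and EGFL7 0.24. TYMS at -0.20, MCM10 at 0.21, APCDD1 at -0.32, CDH2 at -0.29, TGIF1 at -0.26, NDUFV2 at -0.27 and ATP5MC3 at -0.19 moved by over 1.5 times but stayed past the threshold. TYMS, APCDD1, CDH2, TGIF1, NDUFV2, LAMA1, DSC3 and PMAIP1 all lie on chromosome 18. Their falls, given under separate lists above, thus share a chromosome that was lower as a whole.

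**Figure D4:**
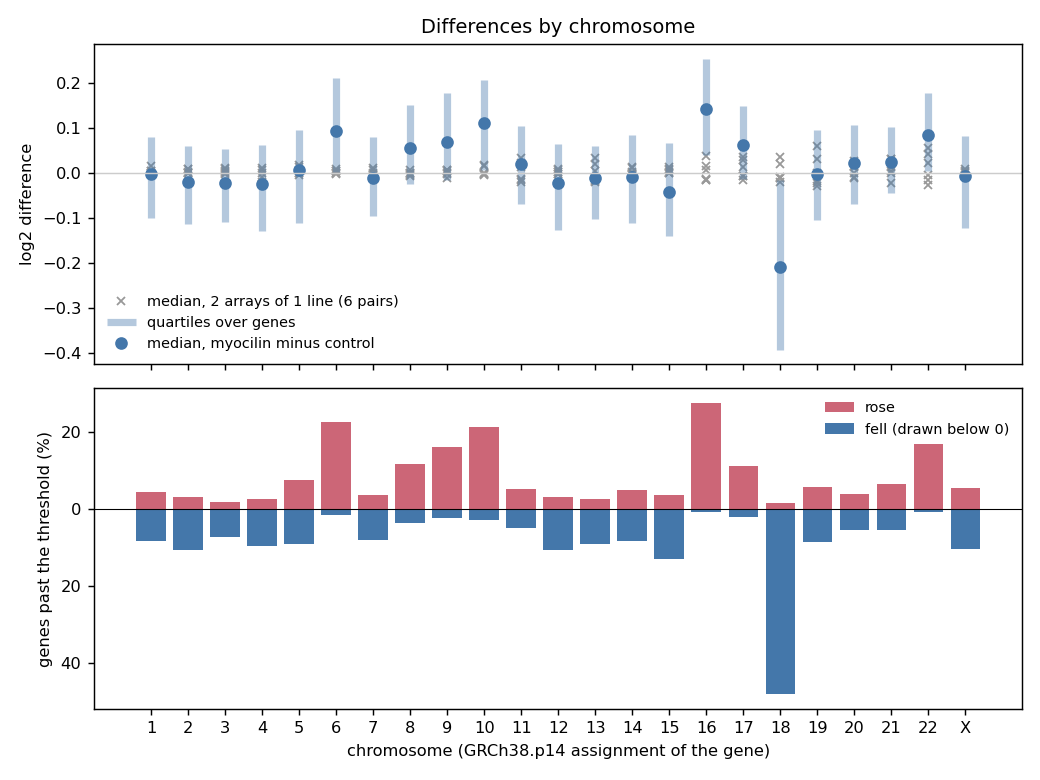
Above, median and quartiles of the log2 difference between lines for each chromosome, with crosses for the 6 pairs of arrays within a line; below, the percentage of genes that rose and, drawn downward, fell. Chromosome 18 stands at -0.21 and chromosome 16 at 0.14, while pairs within a line lie within 0.0383 of 0 on chromosomes 6, 10, 16 and 18.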

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

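No paired analysis was possible because the running numbers in the titles do not repeat between the groups and the labels give no other replicate numbers. The planned filter on dim probe sets and the pseudocounts were not run, since centred log values carry no brightness; for the same reason signal over background limits every low value here. The 1-probe-set, neighbour and chromosome alternatives were chosen after seeing the data. Under quantile normalisation, trend and robust fitting and array weights, 2846, 2740 and 3162 genes were called, sharing 2775, 2710 and 2792 with the 2866 reported, none in the opposite direction. Without probe sets ending in _x_at or _s_at 1878 genes and 5 lists were called, in part because fewer genes were tested. The Welch test called 44 genes and 9 changed at least 2-fold. Camera with an estimated correlation called 0 lists, with 4 at an unadjusted p under 0.05, and fry 13; without chromosomes 6, 10, 16 and 18 there were 5 lists, and the histone call ended at a median of -0.15 (adjusted p = 0.709). HSPB8 read -0.0307 without _x_at and _s_at probe sets and from 1 probe set by ID, AKT2 0.0520 and RPS23 0.0117 by ID; the cause was not tested. A further 28 named genes kept their direction but were no longer past the threshold with 1 probe set by ID, and 15 without _x_at and _s_at probe sets. Minus chromosomal neighbours, 2084 genes and 8 lists were called, sharing 1865 genes, and 19 of 154 named genes were no longer past the threshold. Leaving out 1 array in turn gave 1613 to 2220 genes, 2281 to 3283 probe sets, 51 to 63 genes changed at least 2-fold, 7 to 9 lists and 13 to 15 chromosomes. Probe sets numbered 2281 without myocilin array 1, 2693 without myocilin array 2, 2741 without control array 2, 2789 without myocilin array 3 and 2878 without control array 3. Of 154 named genes 148 passed the threshold, and 9 did so under every alternative that holds them, the Welch test ending most calls.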

Other observations

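The tests of GC content, gene density and single arrays for the chromosome pattern were chosen only after that result was seen, as were the genes named in the next paragraph; the other tests were written before their results were seen. The readings of the tests on adjacent genes, on GC content and on copy number for the ATF4 and histone lists were made stricter after their values were seen.

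Some changed genes not named above, chosen after their values were seen and belonging to no tested list, were as follows. The transcription factor genes SOX8 on chromosome 16 (0.92), NR2E1 on chromosome 6 (0.97) and OLIG1 (0.91) rose. Chromosomes 6 and 16 were also higher as a whole. LHX8 (-1.17), a homeobox factor, the Wnt and BMP antagonist SOSTDC1 (-1.24) and the hormone-like glycoprotein STC1 (-1.06) fell. FSCN1 (1.24), which bundles actin, ANXA1 (1.10), a phospholipid-binding protein, and the carbonic anhydrase gene CA2 (1.15) rose.

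In single genes 1 probe set sometimes stood far from the rest. For CHD2, a chromatin remodeller chosen after its values were seen, 1 probe set read -3.68 while 3 others past the threshold read -0.56 to -0.98.

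Chromosome-wide shifts had medians of -0.21 on chromosome 18, 0.14 on 16, 0.11 on 10 and 0.09 on 6. Signal differences between single arrays are argued against, because the largest median on these 4 chromosomes between 2 arrays of 1 line was 0.0383. That holds for these 4 only: between myocilin arrays 2 and 3 the median was 0.0566 on chromosome 22, against 0.08 between lines, and 0.0596 on 19. Bias that follows GC content stays open: gene-dense chromosome 19 had a median of -0.0024 (95% bootstrap interval -0.0142 to 0.00764), but 16, 17 and 22, also gene-dense, were up. Chromosome 11, denser than 16 and 22, was not called (median 0.0196). The rank correlation of gene density and median over the 23 chromosomes was 0.401 (two-sided permutation test p = 0.058). For DNA copy number, the rank correlation of adjacent genes after removal of chromosome medians was 0.085, above the highest of 1000 shuffles (0.0239), which met the bound written beforehand, but 1 pair of myocilin arrays gave 0.0759 and the other 5 pairs within a line 0.0019 to 0.0257. Copy number, selection of the clones and an effect of myocilin cannot be told apart here, nor can a difference in exposure to doxycycline. Each line is represented once, no DNA measurement was available here and the dose per array is not given.

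For the fall of ATF4 targets, a shift shared with the measured chromosomal neighbours is argued against, as the median was -0.49 after these were subtracted and -0.44 before. This met the bound written beforehand against copy number. It cannot decide on copy number at the targets' own loci, because neighbours without signal would stay near 0 at any copy number. A copy number change elsewhere that acts through a regulator of these genes was not tested. Also argued against is 1 aberrant control array, as the median stayed at or below -0.36 without each control array in turn. A general difference in ER folding stress stays open. The 27 ER genes left without the ATF4-branch genes and ERN1 had a median of -0.10 (95% bootstrap interval -0.126 to -0.028), between the bounds set for either reading. The genes moved together between arrays of a line as well. An effect of myocilin, exposure to doxycycline, medium and cell density at harvest were not tested.

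The shift of the histone list, with 11 of 22 genes higher, includes the cluster on chromosome 6, which as a chromosome was also higher, and H2BC21 on chromosome 1 (0.96). For copy number of the cluster, the 17 histone genes there had a median of 0.35 and the 25 other genes inside the cluster 0.10. The difference of 0.25 (two-sided permutation test p = 0.00159) met the bound written beforehand against copy number as the whole cause. It cannot decide the question, because no detection call could be made and neighbours without signal would stay near 0 at any copy number. The permutation also treated the histone genes as independent. Signal shared between near-identical histone probe sets stays open, since the 13 plain probe sets had a median of 0.25 with a 95% bootstrap interval of -0.0317 to 0.346. The lists of G1/S and DNA replication and of G2/M and mitosis were not called (medians -0.0057 and -0.033, camera adjusted p = 0.635 for both), and an effect of myocilin and polyadenylated histone transcripts were not tested.

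With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each case 1 of the 10 splits, the real one, gave a result as large. The real split gave 2866 genes and the highest other split 0; for probe sets the values were 4603 and 0, for genes changed at least 2-fold 59 and 0, for lists 8 and 5, and for chromosomes 14 and 7.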
